A study of Caenorhabditis elegans with 2 samples.

How the data were processed

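ChIP-seq peak lists of 2 biological replicates of 1 group were used: young adult hermaphrodite worms whose SNPC-3.4 carries a GFP-FLAG tag, fragmented by sonication per the labels. The authors deposited lists of 30000 candidate regions for each replicate and for the pool of both, and a thresholded list, each on ce11 and on ce10. Per the deposited notes, each list was called against a control and the thresholded list is the optimal set by irreproducible discovery rate. The peak caller, the aligner and the mapping filter are not given in the sources used here. The deposited signal value per region has no stated scale, and it ranks regions within a list only. The deposited score column holds values below 0 in the candidate lists and was only described. The summit position is the authors' offset from the start of each region. The thresholded ce11 list was checked to be exactly the 2101 regions of highest signal in the pooled list. On ce10 it held 2066, likewise the highest. The single replicates also feed the pooled list, so they are not independent of it.

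Coordinates are on ce11, which is WBcel235, 1-based. Genes and biotypes came from Ensembl release 115, with RefSeq symbols for 46881 of 46926 genes. Counts on ce10 used no converted coordinate. A summit was given to a class when it lay within 250 bp of an annotated 5' end (500 bp for protein-coding genes). The snRNA class holds entries with that biotype outside the SL RNAs, SmY RNAs included. Mitochondrial genes are in no class. Where peaks are counted once, the order was snRNA, SL RNA, tRNA, snoRNA, other small RNA, piRNA, protein-coding promoter, other. No read counts were in the lists, so depth is unknown, and intervals cover counting error over genes or peaks only.

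Enrichment was tested by 100000 rotations of each chromosome, one-sided. Shares were tested by exact binomial or Fisher's exact tests, medians and correlations by 100000 resamples, and adjustment was by Benjamini-Hochberg within each family. CTGTTTCA was counted within 100 bp of summits and in flanks at 400 to 600 bp on both sides. The planned McNemar test was extended to 2 flanks per peak as an exact matched test, and the flank count was scaled to the length of 1 window. Words of 8 bases within 50 bp of nuclear summits were compared with both flanks at 300 to 400 bp. In a first version these 2 sequence tests used 1 flank per peak, and the overlap of replicates was rotated on lengths longer than the chromosomes. Both were corrected to the planned form after their first results had been seen. The share of unique 31-base words covers 250 bp upstream to 100 bp downstream of a 5' end, and for tRNA gene bodies the words inside the gene. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and, for the figures, matplotlib 3.10.9 were used.

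The classes, windows, 16 gene lists, main tests and the alternatives with stricter, single-replicate, window, flank, merged, cluster-bound and ce10 settings were set before the data were examined. Of the lists, 15 hold protein-coding genes and were tested. The listed symbol snpc-1.5 was not matched in the annotation. Chosen after the data were seen were the tests of summit position, of X against autosomes, of snoRNA host genes and of SmY genes, the split of mitochondrial regions from the planned class of other peaks, the lower tails, the shorter U1 and U2 sequences, unique sequence, and the settings without mitochondrial or small RNA peaks. Named genes are the 10 highest peaks, the 4 highest of each class, every SNAPc, piRNA, transgene and other listed RNA gene, and the 3 highest members of each list that passed. All of the 10 highest peaks were mitochondrial, so the 10 highest nuclear peaks were added afterwards.

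Tests were checked on simulated data. With 20 summits planted among 2101 random ones, the rotation test called snRNA genes in 20 of 20 simulations, tRNA genes in 20 of 20 and piRNA genes in 9 of 20. With 60 planted it called piRNA genes in 20 of 20. With none planted it called them in 1, 1 and 4 of 100. The word search ranked a planted word first in 3 of 3 runs of 2075 summits and passed 0 words in 3 runs without one.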

Results

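The data were chromatin immunoprecipitation and sequencing (ChIP-seq) profiles of SNPC-3.4, a worm homologue of a subunit of the small nuclear RNA activating protein complex (SNAPc), which recruits RNA polymerases to snRNA genes. The protein carried a C-terminal GFP-FLAG tag in Caenorhabditis elegans strain YL497 and was precipitated with an antibody to GFP from whole young adult hermaphrodites. The 2 samples were biological replicates 1 and 2 of 1 group, so no contrast between conditions existed, and the comparisons below are between gene classes and genome regions. The thresholded list held 2101 peaks on ce11, 26 of them mitochondrial. Signal is the value per region that the authors' peak caller gave. Depth is unknown, since the lists hold no read counts. The control named in the deposited notes was not analysed here.

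The strongest nuclear peaks, most of them at small RNA genes, were high in both replicates. The snoRNA gene ZK994.7 had a signal of 336 in replicate 1 and 472 in replicate 2, and the ribosomal protein gene rpl-3 had 230 and 432. Of the 2101 highest regions of replicate 1, 1277 overlapped 1 of the 2101 highest of replicate 2 by at least 1 bp, a share of 60.8% (95% Wilson interval 58.7 to 62.8%). Random rotations of the chromosomes gave 2.23% on average (one-sided permutation p = 1e-05, the smallest that 100000 rotations can give). Signals of the 1913 peaks matched in both replicates had a Pearson r of 0.69 on the log2 scale and a Spearman rho of 0.50, each with a two-sided permutation p of 1e-05. Mitochondrial regions are among them, and the 1893 nuclear peaks alone had 0.616 and 0.481. These are correlations across peaks, which are not independent replicates and were selected on the pooled signal. Of the 2101 thresholded peaks, 69.6% had a summit match among the top regions of replicate 1 and 81.9% among those of replicate 2.

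**Figure D1:**
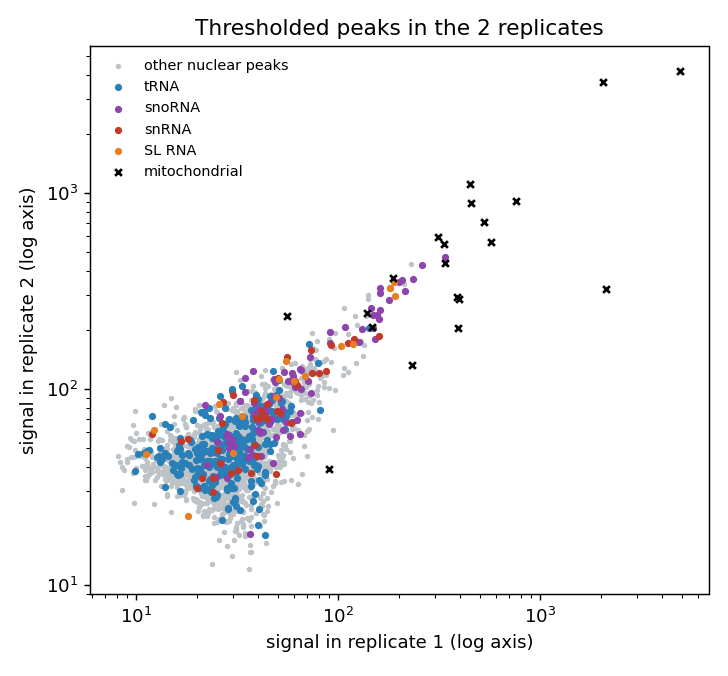
Signal of each thresholded peak in replicate 1 (x) and replicate 2 (y), both on log axes without units, with small RNA classes in colour and mitochondrial regions as crosses. The 1913 peaks with a summit match in both replicates are drawn, and the highest nuclear peak is that of the snoRNA gene ZK994.7 at 336 and 472.

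The first question was which gene classes SNPC-3.4 occupied. Genes of the spliceosomal snRNAs, the SL2 spliced leaders and the snoRNAs, which guide RNA modification, all had peaks beyond chance, as did tRNA genes. Summits within 250 bp of an annotated 5' end numbered 43 at snRNA genes against 1.01 expected by rotation, 17 at SL RNA genes against 0.336, 93 at snoRNA genes against 3.79 and 322 at tRNA genes against 5.13. Each had a one-sided permutation p of 1e-05, the smallest possible (adjusted p = 1.57e-05 over 11 classes). The miRNA genes had 13 summits against 2.39 expected (permutation adjusted p = 1.57e-05). The lincRNA genes had 5 against 2.00 (permutation adjusted p = 0.0719), and rRNA genes had 1 against 0.180 (permutation adjusted p = 0.191), so neither passed.

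**Figure D2:**
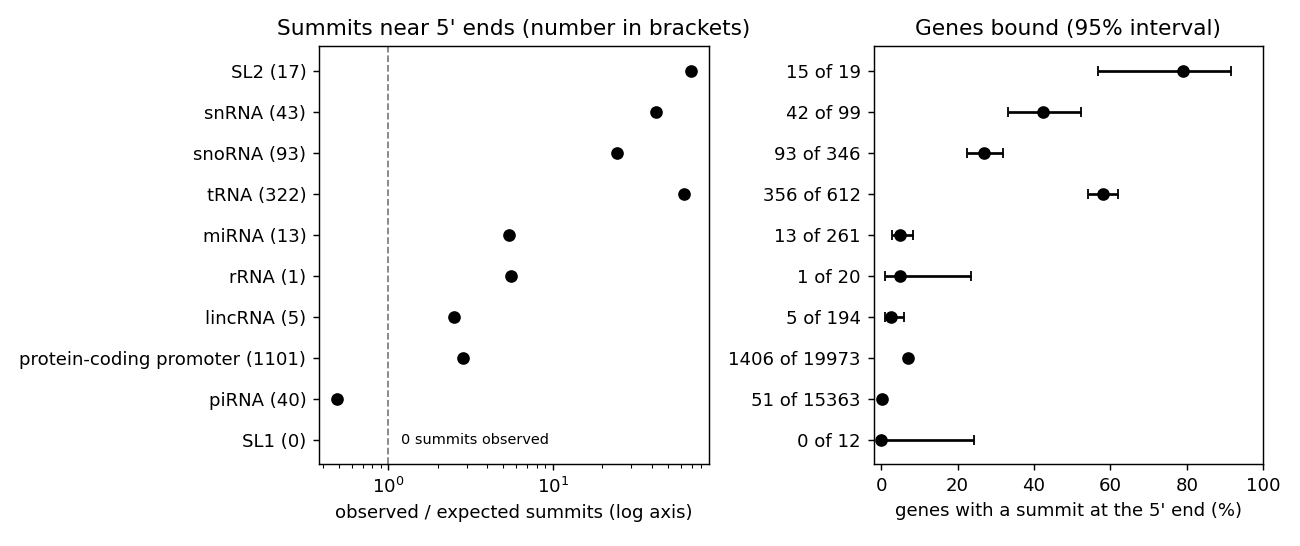
Left, observed over expected number of summits at the 5' ends of each gene class, on a log axis, with the number of summits in brackets and a dashed line at a ratio of 1. Right, the percentage of genes of the class with a summit, with 95% Wilson intervals, highest for SL2 at 78.9% and 0 of 12 for SL1.

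Among 99 snRNA genes 42 were bound, or 42.4% (95% Wilson interval 33.2 to 52.3%), where rotations gave 1.05 genes (permutation p = 1e-05). By conserved sequence, the bound genes were 10 of 11 U5, 4 of 5 U4, 8 of 12 U1, 7 of 19 U2 and 7 of 22 U6 genes, 4 of 10 SmY genes, named by symbol, and 2 of 20 entries that matched no type. The U1 and U2 sequences were shortened after the data were seen, since those fixed first matched no gene. The highest snRNA signals were at F32B5.9, a U5 gene (I, 2688947 to 2689069, signal 351), C52E4.8, a U4 gene (V, 11980118 to 11980261, signal 287), H27M09.6, a U1 gene (I, 6847137 to 6847303, signal 280), and W05B2.8, a U6 gene (III, 10989679 to 10989780, signal 257). Over the replicates, F32B5.9 had a mean signal of 172 ± 18.5 (SD, n = 2) and W05B2.8 129 ± 52.8 (SD, n = 2). Replicate 2 was on a higher scale than replicate 1, which enters each of these SDs. Copies of one U type share sequence, so single members are uncertain: the median share of unique 31-base words was 61.9% at U2 genes and 68.8% at U6 genes.

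Of the spliced leader RNAs, whose 5' ends are joined to mRNAs by trans-splicing, 15 of 19 SL2 entries were bound (78.9%, 56.7 to 91.5%), and 0 of 12 SL1 entries. The median share of unique 31-base words at SL1 genes was 0%, so a lack of peaks there is uncertain. The 4 highest were sls-2.8 (III, 12250465 to 12250575, signal 497), sls-2.16 (III, 7141391 to 7141499, signal 497), sls-2.4 (I, 4172206 to 4172315, signal 494) and sls-2.1 (II, 5844865 to 5844974, signal 482). The SL2 entries included 1 pseudogene, sls-2.19, which had no peak. It is named here after its value was seen.

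The snoRNA genes held 6 of the 10 highest nuclear peaks. ZK994.7 (V, 8500579 to 8500645) had the highest nuclear signal, 820, with its summit in an intron of pxn-1. Y53F4B.47 on II followed at 647, between genes, then W04D2.7 at 584, C16D9.11 at 565 with its summit in an intron of rol-3, C08D8.3 at 558 and Y37E3.20 at 527. Their replicate means ran from 265 ± 70.3 (SD, n = 2) at Y37E3.20 to 404 ± 96.5 (SD, n = 2) at ZK994.7. In all, 93 of 346 snoRNA genes were bound (26.9%, 22.5 to 31.8%).

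Among other RNA genes, rpr-1, the RNase P RNA, had a signal of 353 (I, 13463955 to 13464207) and mrpr-1, the RNase MRP RNA, 144 (II, 7200233 to 7200418). The Y RNA gene yrn-1 had a signal of 87.3, with only 15.4 in replicate 1 against 66.4 in replicate 2, and lay outside the top regions of replicate 1. The rRNA gene rrn-4.15 had 115 (V, 17428879 to 17428996), and rncs-1 had no peak.

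The tRNA genes had the most peaks of the small RNA classes, with 356 of 612 genes bound (58.2%, 54.2 to 62.0%). The highest were C27A2.t1 (II, signal 336), ZC412.t1 (V, 235), Y37A1B.t1 (IV, 227) and R04D3.t2 (X, 163). At R04D3.t2 the replicates had 80.7 and 78.1, and at ZC412.t1 71.9 and 169. Replicate 2 was on a higher scale at tRNA peaks (median log2 ratio 0.851), so like values do not mean closer agreement. By signal, R04D3.t2 held place 96 in replicate 1 and 304 in replicate 2, and ZC412.t1 126 and 72. Copies of a tRNA share their body sequence, so the peak of any single tRNA gene is uncertain.

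Summits lay at different places in these classes. The median summit was 36 bp upstream of snRNA genes, 46 bp upstream of SL2 genes and 49 bp upstream of snoRNA genes, whereas at tRNA genes it was 16 bp inside the gene. The medians were 52, 62 and 65 bp farther upstream than at tRNA genes (two-sided permutation tests chosen after the positions were seen, adjusted p = 1.5e-05, 0.00019 and 1.5e-05, the first and last at the smallest p that 100000 resamples give). A summit 20 to 80 bp upstream was found at 33 of 42 snRNA genes, 15 of 15 SL2 genes, 62 of 93 snoRNA genes and 81 of 356 tRNA genes. At bound protein-coding genes the median summit was 174 bp upstream. These were searched within 500 bp rather than 250 bp, and trans-splicing makes their annotated 5' ends inexact. Their median is therefore not comparable with those of the small RNA classes.

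**Figure D3:**
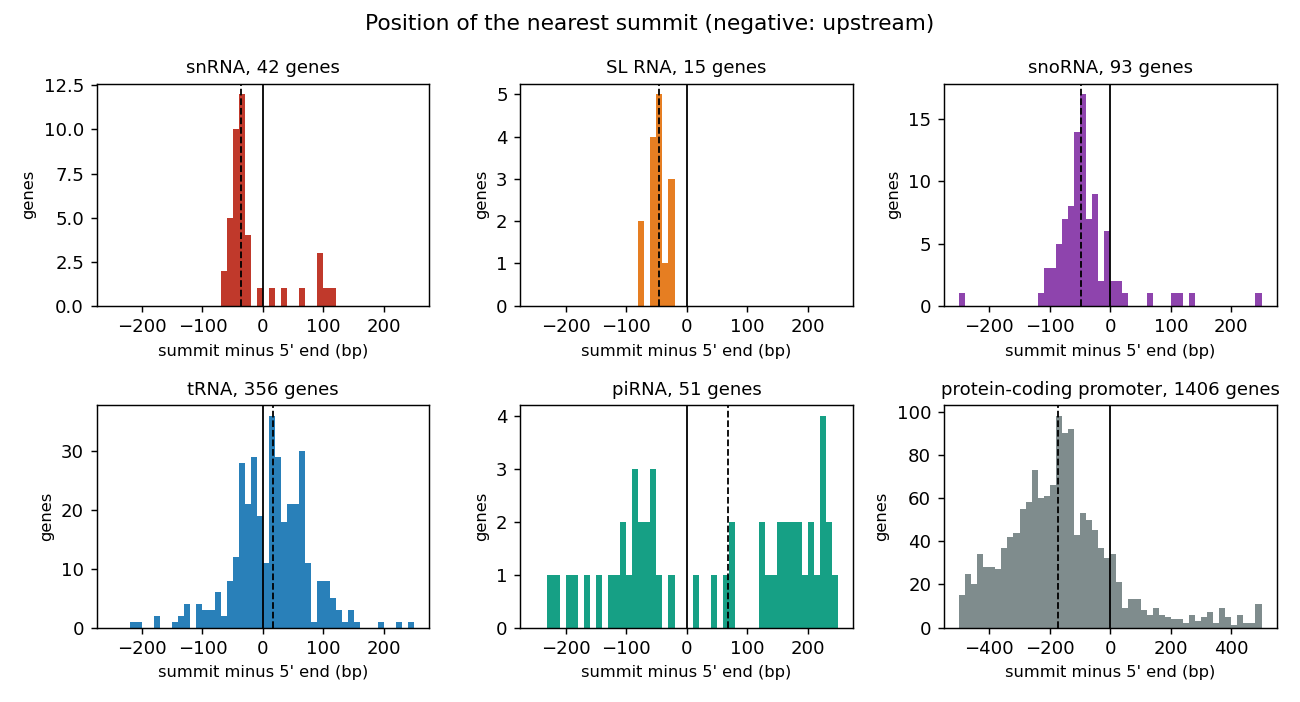
Distance in bp from the annotated 5' end of each bound gene to the nearest summit (x, negative is upstream) and number of genes (y), with solid lines at 0 and dashed lines at the median. The snRNA, SL RNA and snoRNA medians lie 36, 46 and 49 bp upstream, and the tRNA median 16 bp downstream.

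Signal differed by class as well. Taking each peak once, SL RNA peaks had a median signal of 169 (17 peaks), snoRNA peaks 127 (93), other small RNA peaks 129 (4) and snRNA peaks 110 (43), against 70.8 at 1000 protein-coding promoter peaks. The log2 differences of the last 3 were 0.85, 0.86 and 0.64, and the two-sided permutation adjusted p values of the 4 were 2e-05, 2e-05, 0.0197 and 2e-05. At tRNA peaks the median was 76.7 (321 peaks, log2 difference 0.12, permutation adjusted p = 0.0106). At piRNA peaks the median was 72.6 (24 peaks, permutation adjusted p = 0.801), and the 573 nuclear peaks of no class had 64.3 (adjusted p = 0.000112). The calls for tRNA peaks and peaks of no class were lost with replicate 1 alone and with the stricter list, and that for other small RNA peaks with replicate 2 alone and with the stricter list. Those for tRNA and other small RNA peaks were also lost among peaks near 1 class only.

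The second question was whether SNPC-3.4 marked piRNA genes. These are concentrated in 2 clusters on chromosome IV, and their upstream regions carry the sequence CTGTTTCA. Thresholded summits showed no excess in the clusters or at piRNA 5' ends. Weak or broad signal there could not be assessed, since the lists hold no read counts. An excess may also be missed: 20 planted piRNA summits were called in only 9 of 20 simulations. The other simulated summits were random, so they lay near piRNA 5' ends as often as by chance. The real summits lay there less often than that, as given below. More than the planted number could therefore be missed in this list. Of 404 peaks on IV, 148 lay inside the clusters (36.6%, 32.1 to 41.4%), against 35.4% of the chromosome's length (two-sided exact binomial p = 0.640). Inside the clusters, 4 of 148 summits lay within 100 bp of a piRNA 5' end, where rotation within the clusters gave 42.1. Over the genome 40 summits lay within 250 bp of a piRNA 5' end against 82.5 expected (permutation p for enrichment = 1.00), and 51 of 15363 piRNA genes were near a summit. The opposite, lower tail was tested only after these counts were seen, with permutation p = 1e-05 inside the clusters, the smallest possible, and adjusted p = 0.00066 over the genome.

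Of the 24 peaks assigned to piRNA genes alone among small RNA classes, the 4 highest lay outside the clusters, at 21ur-13751 on II (signal 161), 21ur-12279 on I (117), 21ur-11275 on I (116) and 21ur-11631 on I (110). The last of these is also the promoter peak of rps-10 and rpl-24. CTGTTTCA occurred within 100 bp of 15 of 2101 summits and at 36 per equal length of flanks (matched exact p = 0.000728). Inside the clusters it occurred at 0 of 148 summits and 13 per equal length of flanks (matched exact p = 8.09e-06), and outside at 15 and 23 (p = 0.164). Over all peaks the call was lost with a 50 bp window (ratio 0.545, matched exact p = 0.221).

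**Figure D4:**
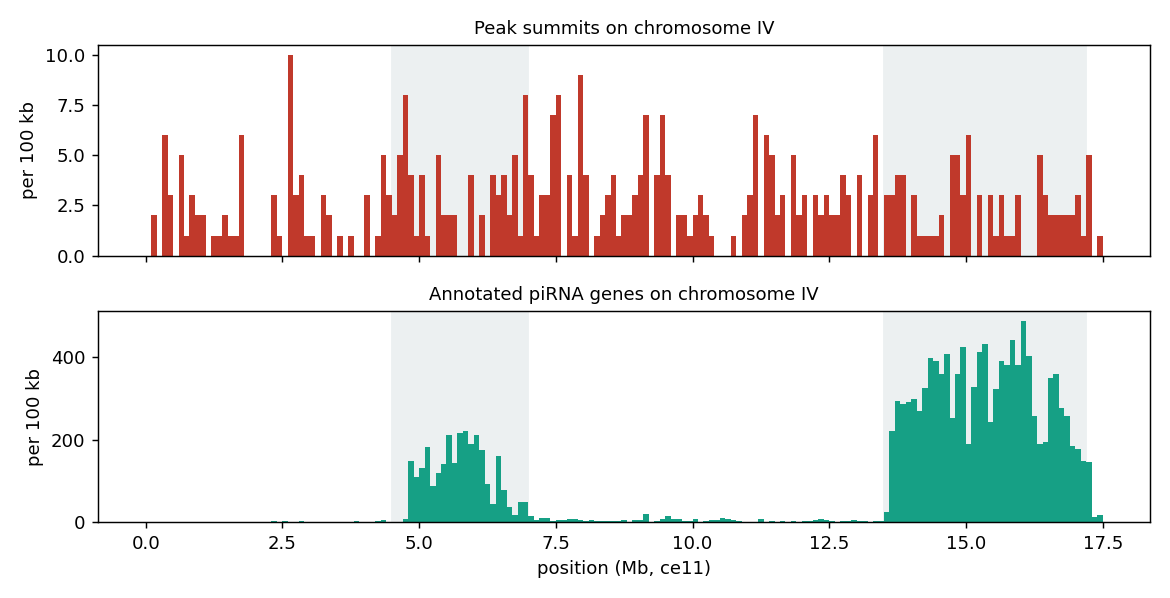
Peak summits (top) and annotated piRNA genes (bottom) per 100 kb along chromosome IV in Mb, with the 2 piRNA clusters shaded. The 14204 piRNA genes inside the clusters contrast with 148 of 404 summits there, close to the share of length.

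Protein-coding promoters held the largest number of peaks. Of all summits 1101 lay within 500 bp of a protein-coding 5' end against 389 expected (permutation adjusted p = 1.57e-05), and 1406 of 19973 genes were bound (7.04%, 6.69 to 7.40%). Besides rpl-3 (III, 3867854 to 3869587, signal 648) and rpl-15 (IV, 653480 to 654576, 556), the highest were cdc-48.1, a AAA ATPase gene (II, 10560036 to 10563407, 538), and Y17G9B.5 (IV, 4750240 to 4751491, 434), whose peak also faced rpl-18A. The 4 highest peaks of no class, named by their nearest gene, were near egrh-2 (signal 349), near col-63 in an exon of ceh-8 (306), in an intron of sre-45 (301) and over linc-154 on X near T01B6.1 (297).

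Among the gene lists, 3 passed. Ribosomal protein genes were bound at 52 of 78 (66.7%, adjusted p = 4.21e-40, two-sided Fisher's exact test adjusted over 15 lists), led by rpl-3, rpl-15 and rpl-18A (signal 434). Sm protein genes, which encode the protein ring of spliceosomal snRNPs, were bound at 6 of 7 (Fisher's exact test, adjusted p = 5.95e-06), led by snr-4 (287), snr-1 (78.9) and snr-6 (69.7). Germline genes were bound at 11 of 28 (39.3%, Fisher's exact test, adjusted p = 7.1e-06), led by syp-4 (280), a synaptonemal complex gene, rec-8 (269), a meiotic cohesin gene, and glh-2 (157). The peak of snr-4 is also that of the U4 gene C52E4.8, and the peak of syp-4 that of the U1 gene H27M09.6. Without peaks at small RNA genes, counts were 45 of 78, 5 of 7 and 10 of 28, and all 3 lists still passed (Fisher's exact test, adjusted p = 3.23e-32, 0.000107 and 4.22e-05). The Sm list did not pass with the stricter list of peaks.

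Genes of other tissues did not pass, nor did the major sperm protein genes, which a later test counts with the germline genes. A lower share could not pass in lists this short, since 7.04% of all protein-coding genes were bound. Even 0 of 31 gave an unadjusted p of 0.167 (Fisher's exact test), so these lists show no excess but cannot show a deficit. Vitellogenin genes were bound at 0 of 6 (Fisher's exact test, adjusted p = 1.00), major sperm protein genes at 0 of 31 (0.268), neuronal genes at 0 of 12 (1.00), intestinal genes at 0 of 11 (1.00), hypodermal genes at 0 of 11 (1.00) and body muscle genes at 1 of 12 (0.796). Collagen genes were bound at 4 of 156 (2.56%, Fisher's exact test, adjusted p = 0.0983), and at 2 of 156 without peaks at small RNA genes (adjusted p = 0.0174, lower than other genes). Histone genes had 9 of 72 (0.246), heat shock genes 4 of 24 (0.246) and basal RNA polymerase III factors 2 of 9 (0.255). Histone and heat shock genes passed with a 1000 bp window, and collagen genes with a 250 bp window.

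Of the SNAPc and piRNA factors, 2 of 11 protein-coding members were bound (Fisher's exact test, adjusted p = 0.268): snpc-3.4 and snpc-4, another SNAPc subunit (signal 55.8), whose peak lay outside the top regions of replicate 1. No peak lay at snpc-1.1, snpc-1.2, snpc-1.3, snpc-3.1, snpc-3.2, prde-1, tofu-4, tofu-5, prg-1 or the pseudogene snpc-3.3. At snpc-3.4 itself (III, 4020037 to 4021883), the tagged gene, the summit was 48 bp upstream of the 5' end, with a signal of 179, place 133 in the pooled list, and 71.3 and 107 in the replicates. At unc-119, often used as a transgene marker, the highest candidate region had a signal of 21.2 at place 20949, with no peak. The transgene list, 1 of 2 genes, did not pass (Fisher's exact test, adjusted p = 0.255).

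Across the nuclear chromosomes, peaks were most in excess of genome length on III (413 peaks, 19.7% against 13.7%, adjusted p = 1.81e-13) and I (395 peaks, 18.8%, adjusted p = 4.07e-06), and fewest for their length on X (205, 9.76% against 17.7%, adjusted p = 7.96e-24) and V (318, 15.1% against 20.9%, adjusted p = 4.36e-11), by two-sided exact binomial tests over 7 chromosomes. Chromosome II had 340 peaks (exact binomial adjusted p = 0.225). Chromosome IV held 404 peaks, 19.2% against 17.4% (exact binomial adjusted p = 0.0389), and this call was lost with the stricter list, with replicate 2 alone and with peaks merged within 10 kb. The binomial tests took peaks as independent, although merging within 10 kb left 1337 regions, so their p values are too small. On X the deficit remained after merging (ratio 0.669, exact binomial adjusted p = 3.22e-08). Merged peaks were not reported for I, III and V.

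On X, promoters and snoRNA genes were bound less often than on autosomes. Protein-coding genes there were bound at 28 of 2731 (1.03%) against 1378 of 17242 on autosomes (7.99%, odds ratio 0.119, Fisher's exact test, adjusted p = 3.75e-56), and snoRNA genes at 3 of 33 against 90 of 313 (adjusted p = 0.0263). The tRNA genes on X were bound at 169 of 276 (61.2%) against 187 of 336 on autosomes (55.7%, Fisher's exact test, adjusted p = 0.250), and snRNA genes at 1 of 3 against 41 of 96 (adjusted p = 1.00). These 4 Fisher's exact tests were chosen after the counts per chromosome were seen.

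**Figure D5:**
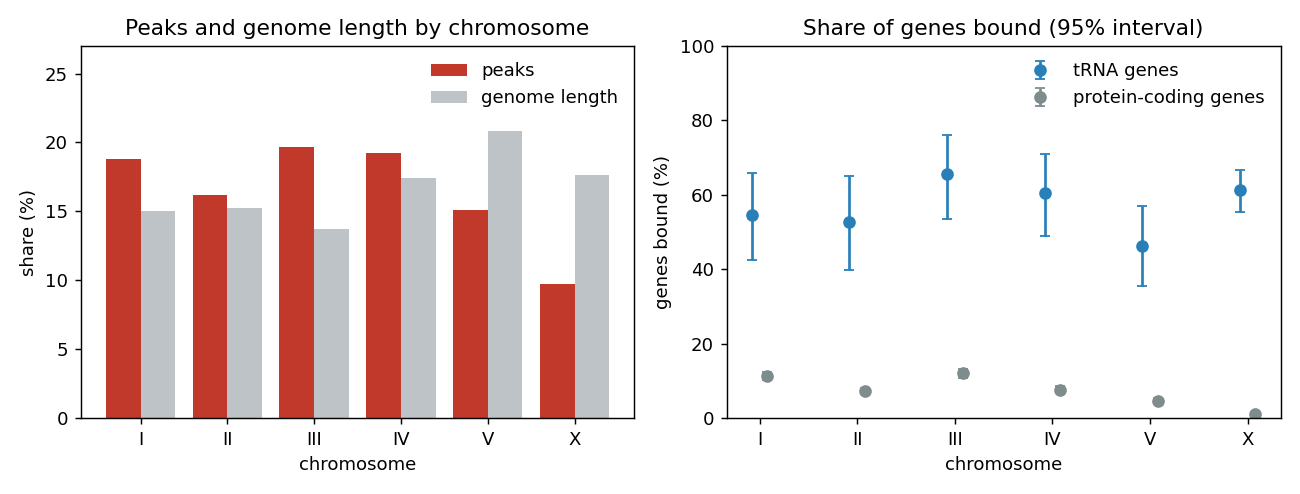
Left, percentage of peaks (red) and of genome length (grey) per nuclear chromosome. Right, percentage of tRNA genes (blue) and protein-coding genes (grey) bound per chromosome with 95% Wilson intervals, where X has 61.2% and 1.03%.

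Sequences at summits were compared with flanks. All 10 of the 8-base words found on I, III and V were enriched on II, IV and X (one-sided Fisher's exact test, adjusted over the 10). Unlike the matched test of CTGTTTCA, it took windows as independent and did not pair a summit with its own flanks. GCGAGACC occurred at 57 of 949 held-out summits and in 6 of 1898 flanks (Fisher's exact test, adjusted p = 1.42e-20), AAAGGCGC at 44 and 13 (adjusted p = 2.27e-11), AAACGCGC at 24 and 4 (adjusted p = 2.19e-08) and GTACGGTA at 23 and 8 (adjusted p = 3.45e-06). CGAGACCC, AAGGCGCA, GCCTTTAA, GCAAACAC, CGCCTTTA and GCGCCAGC completed the set, and several overlap each other.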

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

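Of 94 settings tried on the planned results, 88 left the direction and the side of the threshold, or the count within 1.5 times, as reported. The nuclear-only, mitochondria-unsplit, unique-sequence, typed snRNA and small-RNA-free settings among them were chosen after seeing the data. For summits at gene classes the nuclear-only setting could change nothing, since mitochondrial genes are in no class, yet it counts among the 88. The chromosome IV excess of 1.1 was no longer past the threshold with the stricter list of 1050 peaks (1.08) or with peaks merged within 10 kb (1.02), and ran from 1.05 to 1.1 without each replicate. The stricter list also left 4 classes that differed in signal from promoter peaks, not 7. CTGTTTCA at summits over flanks was 0.545 with a 50 bp window, no longer past the threshold. The Sm list no longer passed with the stricter list. A 1000 bp window gave 5 passing gene lists, not 3. Fewer peaks or hits enter the stricter, merged and 50 bp settings; otherwise the cause was not tested. Ratios for snRNA, SL RNA, tRNA and snoRNA genes stayed far above 1 in every setting, and ratios at piRNA 5' ends stayed below 1. The promoter deficit on X kept its direction in 5 settings chosen afterwards, with odds ratios from 0.0677 to 0.211. Of 99 places of 50 named peaks in single replicates, 96 stayed among the top 2101. The 3 others were yrn-1, snpc-4 and snr-1 in replicate 1, and the mitochondrial region at 5684 to 5788 had no match in replicate 2. Of the 50, C08D8.3 and Y37E3.20 were added after seeing the data. No paired analysis was possible because there is only 1 group. With no read counts, the effect of depth on weak peaks could not be measured.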

Other observations

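The tests of SmY genes, snoRNA hosts, candidate regions at unbound snRNA genes, mitochondrial coverage and signal, tRNA summit position, tRNA and X tRNA genes with their own sequence, tissue lists, X tRNA genes and germline lists were chosen only after the result was seen. SmY RNA genes, whose small RNAs associate with Sm proteins, had 6 summits against 0.120 expected (permutation p = 1e-05, the smallest possible). Of their 12 entries 6 were bound, with a median summit 39.5 bp upstream. The snoRNA genes that do not lie inside a protein-coding gene on the same strand were bound at 58 of 163, against 35 of 183 of those that do (two-sided Fisher's exact test, odds ratio 2.34, p = 0.000656). Of 573 peaks in no class, 293 lay between genes, 174 in exons and 106 in introns, and 34 lay near genes annotated only as ncRNA. Of the 57 snRNA genes without a peak, 22 had a candidate region below the threshold within 250 bp, where rotations gave 7.80 (permutation p = 1e-05, the smallest possible). Among SL1 genes, 0 of 12 had one.

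The enriched 8-base words lay at promoter peaks rather than small RNA peaks in number. GCGAGACC occurred at 95 of 1000 promoter peaks, 11 of 321 tRNA peaks, 1 of 93 snoRNA peaks, 0 of 43 snRNA peaks and 0 of 17 SL RNA peaks. AAAGGCGC occurred at 85 of 1000 promoter peaks, 0 of 321 tRNA peaks, 1 of 93 snoRNA peaks and 0 of 43 snRNA peaks. Nuclear peaks of no class also held them, GCGAGACC at 20 of 573 and AAAGGCGC at 29 of 573. The difference between classes was not tested.

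Hypothesis: bound snoRNA genes may share an upstream sequence with snRNA and SL RNA genes, given their like summit positions. The 5 most enriched 6-base words in the window 20 to 80 bp upstream of 57 bound snRNA and SL RNA genes were AACCCG (31 genes), TGTCGG (28), ACCCGC (27), CGGAAC (22) and GAACCC (21), each in 0 windows at 320 to 380 bp. At least 1 of these words, several of which overlap, was in the same window of 34 of 93 bound snoRNA genes (36.6%) and 12 of 253 unbound ones (4.74%), an odds ratio of 11.57 (two-sided Fisher's exact test, p = 6.82e-13). Farther upstream 2 of the 93 had a word, and 7 of 356 bound tRNA genes (1.97%) had 1 in the near window. The words were found on other genes than those tested, so the result is in line with a shared element, which remains a hypothesis.

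The thresholded list held 26 regions on the mitochondrial genome, which include the 10 highest of all peaks, more than its length gives (exact binomial adjusted p = 1.08e-40). The highest (M, 4355 to 4928) had a signal of 9015, with 4937 and 4189 in the replicates, and the next (M, 12320 to 12577) had 5510, with 2053 and 3694. The third (M, 13057 to 13316) had 2119 in replicate 1 and 321 in replicate 2. The others of the 10 ran down to 1024 at M, 5684 to 5788, which had no match in replicate 2. The median of the 26 was 646, a log2 difference of 3.19 from protein-coding promoter peaks (permutation adjusted p = 2e-05).

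The mitochondrial pattern was weighed against 1 technical explanation, more mitochondrial DNA in the immunoprecipitates than in the control along the whole molecule. All 26 mitochondrial candidate regions passed, against 6.92% of 29974 nuclear candidates, and the 26 covered 44.6% of the 13794 bp, between the bounds of 80 and 30% written for and against this explanation. It therefore cannot be told apart from binding, because the control's own coverage was not analysed here. No biological explanation was tested.

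For the peaks at tRNA genes and ribosomal protein promoters, reads shared between tRNA copies were weighed first. At tRNA genes with a wholly unique body, 4 of 22 were bound, 18.9 times the number by rotation (permutation p = 7e-05). Without another tRNA gene within 1000 bp 2 of 18 were, against 0.187 expected (permutation p = 0.0152). By a bound written afterwards and on few genes, these values argue against reads shared through identical sequence there. A word that differs from a copy by 1 base counts as unique, and the mapping filter is unknown. Reads shared between near copies are therefore not excluded. The bound share was also lower at genes with more unique bodies, as the counts below show. Of 82 genes with a body of their own sequence (50% or more unique 31-base words), 31 were bound (37.8%, 95% Wilson interval 28.1 to 48.6%) against 0.743 expected. Of 63 without such a neighbour 24 were. The lower end of the interval missed the bound written before its value, so shared reads are not excluded for the 82. At the 474 genes with no unique body word, shared reads cannot be told apart from binding, since 305 were bound (64.3%, Fisher's exact test against the 82, p = 8.49e-06), and the median share around the 5' end, 0.625 percentage points higher at bound genes, decides nothing where such genes are the majority of both. The snRNA-type upstream position does not account for most bound tRNA genes, since it held 22.75% of their summits (95% Wilson interval 18.7 to 27.4%) and 8 of 31 at those with their own sequence (13.7 to 43.2%), against 78.6% at snRNA genes. A peak at every promoter strongly transcribed in some tissue was not seen, since vitellogenin, body muscle and intestine genes together had 1 of 29 bound (3.448%) against 52 of 78 ribosomal protein genes (Fisher's exact test, p = 1.23e-09). Genes on X, where few promoters were bound, were not left out of this count. Signal of promoters used in 1 tissue may also stay below the threshold in whole worms, so weaker signal there is not excluded. Signal that an antibody to GFP gives at open chromatin in untagged animals stays open, since no such control was analysed here.

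For the few promoter peaks on X, fewer calls over the whole chromosome would also lower tRNA genes, and the share of X tRNA genes bound was 1.1 times that on autosomes. This does not exclude it, since reads of autosomal copies may reach X tRNA genes: of those with a body of their own sequence, 9 of 27 were bound on X and 22 of 55 on autosomes (Fisher's exact test, p = 0.633), and snoRNA genes were bound less often on X (3 of 33 against 90 of 313, adjusted p = 0.0263). The other candidate explanation is that promoters used in the germline, where X is known to be little transcribed, carry the peaks. Among autosomal genes of the lists, 11 of 28 germline genes were bound against 1 of 37 muscle, neuronal, intestinal and hypodermal genes, an odds ratio of 23.29 (Fisher's exact test, p = 0.000205), or 8.25 (p = 0.0259) with the major sperm protein genes, of which 0 of 31 were bound, added to the germline genes. The ribosomal and Sm protein lists were bound as well, and no test compared germline use with broad use in all cells, so both stay open.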
